A study of Mus musculus with 69 samples.

How the data were processed

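The data were 69 RiboTag RNA-seq libraries of mouse cortex in 8 groups set by cell class, genotype and cortical area. In RiboTag mice, Cre recombination adds an HA tag to the ribosomal protein RPL22 in a chosen cell class, and immunoprecipitation of the tag from homogenate recovers the mRNA bound to ribosomes of those cells together with some RNA of other cells. Per the labels' protocols, tissue was dissected from 1.5 mm coronal slices, lysed with cycloheximide, and the RNA had an integrity number of at least 7, and libraries were made with Ovation RNA-Seq System V2, which amplifies cDNA without molecular identifiers, and sequenced as paired-end reads of 100 bases. Only immunoprecipitated libraries entered the comparisons; homogenate RNA was not analysed here.

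The authors deposited a single table of estimated counts of reads per gene, with 1 column per library and no normalization, and 71.1% of its values were not whole numbers. The submitters' processing notes name STAR, Salmon and limma and the mm10 genome build. The role of each tool, versions, the order of the steps and the annotation release were not given in the sources used here. Estimated counts share reads between transcripts with common sequence, so genes of clusters with shared exons, such as the gamma protocadherins, carry uncertain values, and the kit does not by itself separate reads from overlapping genes on opposite strands. The table held 17634 genes. Every gene had an estimated count above 0 in at least 17 libraries and reached at least 6.0 in some library, so low genes had been left out by a rule not given in the sources used here. Gene identifiers were matched to GENCODE release M21, which named 17614 of them and left 20 without a symbol. Library totals ranged from 27.64 to 49.11 M estimated counts with a median of 38.77 M. No PCR duplicates could be recognised from counts, so the errors given are between animals and not counting errors.

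Samples were grouped by the genotype, cell class, area and sex in the labels. The library names carry animal codes. Of 37 codes, 32 had both a V1 and an S1 library. Within each group, every pair of libraries differed by far more than counting noise, with a smallest chi-square per degree of freedom of 4.58, so no library was present a second time. Groups, tests, covariates, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Estimated counts were rounded to whole numbers, and genes were filtered with filterByExpr. Libraries were scaled with TMM factors, and edgeR 4.0.16 (R 4.3.3) was run with the robust quasi-likelihood fit, glmQLFTest, sex as a covariate and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and every adjusted p of a single gene below comes from this test unless another tool is named. KO was compared with WT in each class and area, and in each class over both areas with the libraries of an animal summed so that each animal counted once. The difference of the genotype effect between classes was tested on the summed animals, and its difference between areas on single libraries. WT libraries were also compared between classes and between areas. CPM values were computed from the rounded counts.

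Named genes followed a rule. Fmr1 and Rapgef4 were always named, together with the 10 called genes with the largest fold change in each direction among those with a mean of at least 5 CPM, and up to 2 called members per gene list and direction with the smallest p. Comparisons between classes and areas in WT had shorter rules of the same kind, with named markers per list or 5 genes per direction, and the text names only some of the genes the rules gave. A few of them are not reported here. For comparisons without a called gene, the 5 genes with the smallest p in each direction were taken. Beside a named gene, unless another share is given, all KO libraries or animals lay on the stated side of the WT mean, or all PV libraries on the stated side of the Camk2a mean. Where the median, mean and test of a list differed in sign outside the summed animals, the list had not passed.

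The 26 gene lists were markers of PV interneurons, other interneurons, excitatory neurons, astrocytes, oligodendrocytes, their precursors, microglia, vascular cells and red blood cells, and lists of commonly cited FMRP target mRNAs, cAMP and EPAC signalling, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, translation factors and the mTOR pathway, GABA synapses, glutamate receptors and the postsynaptic density, vesicle release, voltage-gated potassium channels, sodium, calcium and HCN channels, activity-regulated genes, perineuronal nets, proteasome and ubiquitin, cholesterol synthesis, chromatin regulators, and heat shock and stress. Of their members, 3 (Alas2, Has2 and Otx2) were not in the table. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, with fry, and by exact permutation tests on a score per animal (mean log2 CPM with a prior count of 2). The FMRP list came from general knowledge and not from these samples. For a list's median, 10000 random lists matched on mean expression and exon length from 100 neighbours of each member gave a reference.

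The code was tested on simulated counts with 200 genes changed by 1.25, 1.5, 2 or 3 fold at the real means and library sizes. Of genes changed 1.5 fold, 74% were recovered in the PV V1 simulation, 90% in PV S1, 82% in Camk2a V1, 74% in Camk2a S1, 80% in the summed PV animals, 74% in the summed Camk2a animals, and 68% for the difference between classes. Genes simulated without a change made up 1.3% to 6.9% of the calls. Simulated genes were drawn independently, without genes that vary together or pairs of libraries from an animal. These shares therefore do not measure false calls in the real data.

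Whether the animal codes pair V1 and S1 libraries was checked with deviations from the group means over 10670 genes. The codes come from the library names, and the labels gave no code with conflicting sex or genotype. Same-code libraries correlated with a median of 0.347 (-0.223 to 0.635) over 19 PV pairs, 15 of them above 0.1, and 0.504 (-0.088 to 0.861) over 13 Camk2a pairs, 12 of them above 0.1. The V1 library correlated best with the S1 library of its own animal in 8 of 19 PV and 9 of 13 Camk2a animals. Because both libraries come from the same animal, blocked fits are given where they change a call or move a count by more than 1.5 times.

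Alternatives set in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, no sex covariate, a glial marker score as an added covariate, the block on the animal code (edgeR between areas, and limma-voom on libraries kept apart in place of summed animals), leaving out the single library whose batch label is Batch 2, leaving out each library or animal in turn in the genotype comparisons, genes of at least 5 CPM for correlations, and an estimated correlation for lists. After the data had been seen, sex by Y-linked genes, leaving out 3 Camk2a animals rich in PV markers, and leaving out animals whose libraries lay on the other area's side of an area score were added, as were permuted genotypes for correlations among genes of at least 5 CPM and for counts of shared calls. A library counted as male above 20 CPM of Y-linked genes. The area score used 100 genes per score with a mean of at least 3 log2 CPM. Other splits of the samples were drawn 100 times per comparison.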

Results

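Ribosome-bound mRNA was measured in parvalbumin (PV) interneurons and in Camk2a-expressing neurons of mice 70 to 100 days old, in primary visual (V1) and primary somatosensory (S1) cortex. PV interneurons are fast-spiking inhibitory cells, and cortical Camk2a neurons are mainly excitatory pyramidal cells. Mice were WT or lacked Fmr1, the gene whose silencing in humans leads to fragile X syndrome. The design asks what loss of its product, the RNA-binding protein FMRP, does to the mRNAs on ribosomes of inhibitory and excitatory neurons. PV libraries came from 10 animals in each of the 4 combinations of genotype and area. Camk2a libraries came from 8 WT and 6 KO animals in V1 and from 8 WT and 7 KO animals in S1. Mean library totals, in M estimated counts, were 36.11 ± 2.24 (SD), 38.87 ± 3.98, 37.32 ± 5.26 and 37.86 ± 3.84 in PV WT V1, KO V1, WT S1 and KO S1. They were 40.53 ± 2.35, 43.3 ± 3.32, 41.01 ± 6.95 and 42.25 ± 3.93 in the same order for Camk2a.

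Fmr1 was low in every KO library. This gene (ENSMUSG00000000838, chromosome X, 68678541 to 68717963, plus strand, mm10) lay at 43.46 ± 4.11 CPM (SD, n = 10) in WT and 10.4 ± 2.03 CPM (n = 10) in KO PV V1 libraries. In PV S1 it lay at 44.94 ± 5.06 and 9.795 ± 1.62 CPM (n = 10 each). Camk2a neurons held more of it in WT, with 84.42 ± 7.28 CPM (n = 8) in V1 and 77.75 ± 6.89 CPM (n = 8) in S1. KO values were 8.479 ± 1.54 CPM (n = 6) and 8.65 ± 0.862 CPM (n = 7). The highest KO library of any group, at 14.74 CPM, lay below the lowest WT library, at 35.93 CPM. Log2 fold changes were -2.05 (SE 0.095, adjusted p = 2.72e-12) in PV V1, -2.18 (SE 0.087, adjusted p = 7.54e-15) in PV S1. They were -3.31 (SE 0.099, adjusted p = 3.98e-12) in Camk2a V1 and -3.15 (SE 0.075, adjusted p = 3.95e-14) in Camk2a S1.

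**Figure D1:**
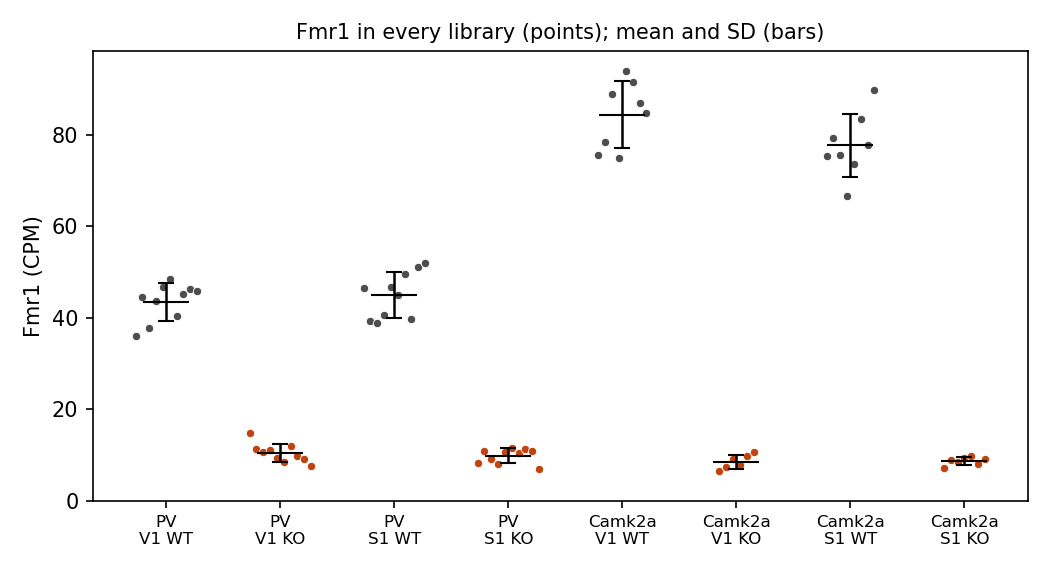
Fmr1 in CPM (y axis) in every library of the 8 groups (x axis). Points are libraries and bars give the mean and SD; all KO libraries lie at or below 14.74 CPM and all WT libraries at or above 35.93 CPM.

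Rapgef4 (ENSMUSG00000049044, chromosome 2, 71981240 to 72257474, plus strand) encodes EPAC2, a cAMP-activated exchange factor for Rap that the series names as a therapeutic target. It lay above the WT mean in most KO libraries but passed the adjusted test in no genotype comparison. Its level was 300.3 ± 15.4 CPM (SD, n = 10) in WT and 327.4 ± 21.1 CPM (n = 10) in KO PV V1 libraries, and 318 ± 13.5 and 337 ± 16.2 CPM (n = 10 each) in PV S1. Camk2a libraries held 214.1 ± 21.8 (n = 8) and 236.4 ± 16.5 CPM (n = 6) in V1, and 243 ± 12.6 (n = 8) and 280.9 ± 25.7 CPM (n = 7) in S1. The log2 fold change was 0.13 (adjusted p = 0.234, higher in 9 of 10) in PV V1, 0.10 (adjusted p = 0.209, 9 of 10) in PV S1. It was 0.14 (adjusted p = 0.306, 5 of 6) in Camk2a V1 and 0.20 (adjusted p = 0.0547, 7 of 7) in Camk2a S1. With both areas of an animal summed it was 0.12 (SE 0.032, adjusted p = 0.0651, 8 of 9 KO animals) in PV and 0.15 (SE 0.051, adjusted p = 0.103, 5 of 6 KO animals) in Camk2a. It crossed the threshold in Camk2a S1 with DESeq2 (0.20, adjusted p = 0.0139), without the sex term (0.21, adjusted p = 0.0326), without C24 (0.19, adjusted p = 0.0457) and without C4 (0.22, adjusted p = 0.0327). Its adjusted p ranged over 0.0139 to 0.0884 across other settings and 0.0327 to 0.153 across libraries left out. In the summed animals it crossed in PV with DESeq2 (0.12, adjusted p = 0.0068), with a glial score (0.12, adjusted p = 0.0349), with limma-voom on libraries kept apart and the animal as a block (0.11, adjusted p = 0.0092) and without P5 (0.13, adjusted p = 0.0494). The ranges were 0.0068 to 0.0908 and 0.0494 to 0.146. In Camk2a it crossed with the same limma-voom fit (0.18, adjusted p = 0.0192), over a range of 0.0192 to 0.289.

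In PV interneurons of KO animals, Gng4, a G protein gamma subunit, rose by a log2 fold change of 0.71 (SE 0.086, adjusted p = 5.10e-05). Gjd2, which encodes the connexin of gap junctions between these cells, rose by 0.31 (SE 0.048, adjusted p = 8.11e-04), and Cd99l2, a membrane glycoprotein gene on chromosome X near Fmr1, by 0.49 (SE 0.032, adjusted p = 1.03e-09). Klhl14 fell by 0.86 (SE 0.1, adjusted p = 2.89e-05), the phospholipase C gene Plch1 by 0.61 (SE 0.047, adjusted p = 2.73e-08). The Ras-association gene Rassf4 fell by 0.51 (SE 0.055, adjusted p = 9.73e-06) and Nos1, the neuronal nitric oxide synthase, by 0.54 (SE 0.105, adjusted p = 0.0099). Of calcium channel genes, Cacna1i fell with a log2 fold change of -0.34 (adjusted p = 0.0041) and Cacna1h with -0.35 (adjusted p = 0.0476, lower in 8 of 9), while Cacna1g, looked at after its value was seen, stood at -0.02 (adjusted p = 0.979). The Cacna1h call ended with RLE size factors (adjusted p = 0.0515), without a filter on low counts (0.0514) and without the sex term (0.0591). Spp1, the secreted protein osteopontin, also fell (log2 fold change -0.62, adjusted p = 0.0379).

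Summed over both areas, 234 of 17154 genes differed between 9 KO and 10 WT PV animals, 54 higher and 180 lower in KO. Among the listed groups, the potassium channel genes Kcng4 (-0.44, adjusted p = 0.0049) and Kcnb2 (-0.31, adjusted p = 0.0098) fell. So did the GABA receptor subunit Gabra5 (-0.27, adjusted p = 0.0195) and the vesicle protein gene Rph3a (-0.29, adjusted p = 0.0051). Lower values were also called for the cyclic nucleotide phosphodiesterase Pde1b (-0.16, adjusted p = 0.0134), the adhesion receptor Adgrb2 on the FMRP list (-0.17, adjusted p = 0.0132) and the chromatin gene Auts2 (-0.20, adjusted p = 0.0202). Of other cells' markers, the Ras exchange factor Rasgrf2 (-0.24, adjusted p = 0.0071) and the myelin lipid enzyme Ugt8a (-0.35, adjusted p = 0.0102, 8 of 9) fell. The count was 476 with DESeq2, 384 with a glial score and 411 with limma-voom on libraries kept apart and the animal as a block, of which 193 were among the 234. Without the KO animal P9 it was 144 and without the KO animal P10 145. Several calls ended in that limma-voom fit, in which the tool, the unit and the block change together. Nos1 (-0.54, adjusted p = 0.0515), Spp1 (-0.72, adjusted p = 0.201), Cacna1h (-0.38, adjusted p = 0.180), and Kcng4 (-0.46, adjusted p = 0.279) no longer passed, nor did Kcnb2 (-0.31, adjusted p = 0.136), Gabra5 (-0.26, adjusted p = 0.153) and Ugt8a (-0.37, adjusted p = 0.135).

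Activity-regulated genes, whose transcription follows neuronal firing, lay low together in KO PV animals. Of 30 members, 28 had negative values with a median log2 fold change of -0.39, none was called over all genes or adjusted over the list alone, and the list passed camera (adjusted p = 4.21e-09, adjusted p = 0.752 with an estimated correlation). Heat shock and stress genes were negative in 22 of 24 (median -0.06, 0 called over all genes, 4 lower adjusted over the list alone, adjusted p = 1.93e-04, adjusted p = 0.752 with an estimated correlation). Cytosolic ribosomal protein genes were negative in 68 of 78 (median -0.06, adjusted p = 0.0034) and the mitochondrially encoded genes in 13 of 13 (median -0.32, adjusted p = 0.0210), both with 0 called and with adjusted p = 0.868 with an estimated correlation. Potassium channel genes were negative in 28 of 40 (adjusted p = 0.0175, 2 lower on either adjustment, adjusted p = 0.752 with an estimated correlation). Genes of cAMP and EPAC signalling were negative in 26 of 42 (adjusted p = 0.0256, 1 lower over all genes, 1 higher and 5 lower adjusted over the list alone), with adjusted p = 0.752 with an estimated correlation. Glutamate receptor and postsynaptic density genes were negative in 37 of 53 (adjusted p = 0.0227, 1 lower over all genes and 3 adjusted over the list alone, adjusted p = 0.868 with an estimated correlation). On scores per animal, exact permutation tests gave a KO minus WT difference of -0.47 for activity-regulated genes (p = 0.0422, adjusted p = 0.487, lower in 7 of 9 KO animals). For heat shock genes the same permutation test gave -0.14 (p = 0.0116, adjusted p = 0.301, 9 of 9). No list separated the genotypes after adjustment over the 26 lists.

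Commonly cited FMRP target mRNAs were negative in 48 of 77 in PV (median -0.02, 1 lower on either adjustment) and chromatin regulators in 28 of 42 (median -0.03, 1 lower over all genes, 2 adjusted over the list alone), and neither list passed (adjusted p = 0.121 and 0.0731). With a glial score both passed toward lower values (median -0.03 each, adjusted p = 0.0208 and 0.0185). Markers of other cells did not pass without that score. PV markers themselves had a median of -0.01 (adjusted p = 0.798) and excitatory markers 0.01 (adjusted p = 0.798). Astrocyte markers were positive in 13 of 18 (median 0.07, adjusted p = 0.143), and microglia markers in 9 of 15 (median 0.08, adjusted p = 0.121). So were vascular markers in 12 of 16 (median 0.06, adjusted p = 0.190) and red blood cell markers in 4 of 4 (median 0.74, adjusted p = 0.119). Oligodendrocyte markers were negative in 12 of 17 (median -0.07, adjusted p = 0.147) and passed toward lower values with a glial score (median -0.09, adjusted p = 0.0307). That score is itself a measure of glial markers, so a fit with it is no independent test of a glial list. For other interneuron markers (median 0.03, mean -0.03, adjusted p = 0.596), oligodendrocyte precursor markers (median 0.01, mean -0.01, adjusted p = 0.798) and excitatory markers (mean -0.02) the mean and the test were negative while the median was positive. The same held for sodium, calcium and HCN channel genes (median 0.02, mean -0.00), and for vesicle release and proteasome genes the test alone was negative.

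Area by area, PV interneurons gave 31 of 16246 genes in V1 (2 higher, 29 lower) and 122 of 15838 in S1 (36 higher, 86 lower). Apart from Fmr1, the lists of called genes shared 20 genes, all of the same sign, among them Cd99l2, Klhl14, Plch1, the nicotinic receptor subunit Chrna4 and the transcription factor gene Nfatc2. Of these, 19 fell in both areas. V1 and S1 libraries come mostly from the same animals, and with genotypes permuted over animals the lists shared 0 genes in each of 100 draws. Without the animals on the other area's side Nfatc2 no longer passed in V1 (-0.43, adjusted p = 0.0634). In V1, Klhl14 fell by 0.97 (adjusted p = 1.79e-05), Nell1, a secreted protein gene, by 0.63 (adjusted p = 2.76e-04). The histamine receptor Hrh2 fell by 0.49 (adjusted p = 0.0085) and Chrna4 by 0.43 (adjusted p = 0.0296), and Gjd2 rose by 0.42 (adjusted p = 0.0146). In S1, Gng4 rose by 0.90 (adjusted p = 0.0041) and Ighm, an immunoglobulin gene, by 0.63 (adjusted p = 0.0052). The steroid enzyme gene Akr1c18 (-0.60, adjusted p = 0.0053), Rassf4 (-0.59, adjusted p = 2.36e-04) and Chrna4 (-0.52, adjusted p = 0.0074) fell. Activity-regulated genes were negative in 30 of 30 in V1 (median -0.40, adjusted p = 6.41e-06, adjusted p = 0.901 with an estimated correlation) and in 27 of 30 in S1 (median -0.20, adjusted p = 0.0014, adjusted p = 0.751 with an estimated correlation). Heat shock genes were negative in 21 of 24 (adjusted p = 3.26e-04, 0.871 with an estimated correlation) and 21 of 23 (adjusted p = 0.0014, 0.751 with an estimated correlation). In V1 the lists of ribosomal proteins (4.00e-06), mitochondrially encoded genes (2.14e-04), and glutamate receptors (0.0046) also passed toward lower values at these adjusted p. So did chromatin regulators (0.0046), FMRP targets (0.0171) and cAMP signalling (0.0304). None of them had a called member, and they stood at adjusted p between 0.871 and 0.932 with an estimated correlation. The V1 libraries of P9 and P24 (KO) and of P22 (WT) lay on the S1 side of the area score. Activity-regulated, mitochondrially encoded, glutamate receptor, chromatin and FMRP lists were higher in V1 than in S1 in WT PV libraries. Whether this imbalance of areas adds to the V1 list results was not tested, as no list was refitted without these animals. In S1, vascular markers were positive in 13 of 15 (median 0.20, adjusted p = 0.0084) and microglia markers in 13 of 15 (median 0.17, adjusted p = 0.0409), each with adjusted p = 0.751 with an estimated correlation.

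In V1 the PV count was 113 with DESeq2, 137 with a glial score, 48 with sex by Y-linked genes, 20 without the WT library P26 and 56 without the WT library P22. In S1 it was 308 with DESeq2, 80 without the KO library P24 and 81 without the animals whose libraries lay on the other area's side.

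In Camk2a neurons of KO animals, Cdkn1c, a cyclin-dependent kinase inhibitor, rose by a log2 fold change of 1.2 (SE 0.166, adjusted p = 0.0029), and Fam160a1 by 1.04 (SE 0.157, adjusted p = 0.0042). Sphkap, which anchors protein kinase A, rose by 0.80 (SE 0.156, adjusted p = 0.0183) and the serotonin receptor Htr1a by 0.67 (SE 0.146, adjusted p = 0.0276). The D-type cyclin Ccnd2 fell by 0.86 (SE 0.113, adjusted p = 0.0021), as did the G protein regulator Rgs16 by 1.02 (SE 0.174, adjusted p = 0.0083) and the neuropeptide precursor Cartpt by 1.0 (SE 0.172, adjusted p = 0.0084). Tcap (-1.46, SE 0.191, adjusted p = 0.0023), Tnnc1 (-1.38, SE 0.243, adjusted p = 0.0113) and Tnnt2 (-0.89, SE 0.127, adjusted p = 0.0031), which encode sarcomere proteins, also fell, as did the matrix gene Abi3bp (-1.44, SE 0.212, adjusted p = 0.0050). Pcdhga9, Pcdhgb7 and Pcdhgb5 rose by 0.68, 0.67 and 0.65 (adjusted p = 0.0038, 0.0084 and 0.0219), values that are uncertain because genes of this protocadherin cluster share their constant exons.

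Over both areas, 688 of 16743 genes differed between 6 KO and 7 WT Camk2a animals, 344 higher and 344 lower. FMRP-listed genes that rose included the ubiquitin ligase Herc1 (0.40, adjusted p = 0.0264) and the membrane adaptor Ank2 (0.37, adjusted p = 0.0335). The presynaptic scaffold Pclo (0.43, adjusted p = 0.0444), the mTOR partner Rptor (0.32, adjusted p = 0.0232), the kinase Rps6kb2 (0.37, adjusted p = 0.0474), the potassium channel subunit Kcns2 (0.44, adjusted p = 0.0038) and the histone methyltransferase Setd2 (0.44, adjusted p = 0.0099) rose. The channel subunits Kcnmb4 (-0.27, adjusted p = 0.0306) and Cacnb3 (-0.22, adjusted p = 0.0386), the cholesterol genes Stard4 (-0.41, adjusted p = 0.0083) and Cyp51 (-0.35, adjusted p = 0.0386) and the stress factor Ddit3 (-0.71, adjusted p = 0.0427) fell. Of other cells' markers, the astrocyte genes Aldoc (-0.84, adjusted p = 0.0019) and Aldh1l1 (-0.35, adjusted p = 0.0357), the myelin gene Mbp (-0.41, adjusted p = 0.0336) and the smooth muscle gene Tagln (-1.89, adjusted p = 0.0063, mean 0.913 CPM) were lower.

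Such counts in Camk2a depended strongly on single animals and on the tool. For both areas the count was 1743 with DESeq2, 1949 with limma-voom on libraries kept apart and the animal as a block, 608 of them among the 688. It was 1347 without C24, whose S1 library is the only one of Batch 2, and 131 without C3, C18 and C19, which are rich in PV markers. Of those 131, 118 were among the 688, and 687 of the 688 kept their sign. Without these 3 animals Sphkap (0.73, adjusted p = 0.114), Htr1a (0.73, adjusted p = 0.0899), Tnnc1 (-1.38, adjusted p = 0.0818), Rgs16 (-1.0, adjusted p = 0.0714) no longer passed. The same held for Herc1 (0.36, adjusted p = 0.0989), Ank2 (0.36, adjusted p = 0.106), Setd2 (0.45, adjusted p = 0.0581) and Stard4 (-0.42, adjusted p = 0.0581). Other calls that ended were those of Pclo (0.38), Rptor (0.30), Rps6kb2 (0.33), Kcnmb4 (-0.30), Cacnb3 (-0.24) and Cyp51 (-0.33). So did those of Ddit3 (-0.72), Aldh1l1 (-0.36), Mbp (-0.45), Tagln (-1.81) and Pcdhgb5 (0.66). These log2 fold changes lay near those with all animals. Calls that held included those of Cdkn1c (1.37, adjusted p = 0.0155), Ccnd2 (-0.96, adjusted p = 0.0016), Tcap (-1.40, adjusted p = 0.0035), Aldoc (-0.77, adjusted p = 0.0192) and Kcns2 (0.48, adjusted p = 0.0162). Those of Fam160a1 (0.93), Abi3bp (-1.45), Tnnt2 (-0.84), Cartpt (-1.14), Pcdhga9 (0.72) and Pcdhgb7 (0.65) held as well. With a glial score the Pclo call ended (0.42, adjusted p = 0.0664), and without a filter on low counts that of Rps6kb2 (0.36, adjusted p = 0.0514). In the limma-voom fit with the block Cartpt did not pass (-0.85, adjusted p = 0.339). Leaving out other animals gave 1071 (C14), 368 (C4), 318 (C5), 372 (C20), 332 (C19), 272 (C23), 270 (C15), 235 (C7) and 235 (C16).

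Several groups of mRNAs lay low in Camk2a KO animals. Cytosolic ribosomal protein genes were negative in 76 of 78 (median -0.15, 0 called over all genes, 16 lower adjusted over the list alone, adjusted p = 2.85e-12) and nuclear-encoded oxidative phosphorylation genes in 68 of 77 (median -0.14, 0 called on either adjustment, adjusted p = 6.72e-07). Cholesterol synthesis genes were negative in 22 of 25 (median -0.21, 2 lower over all genes, 14 lower and 1 higher adjusted over the list alone, adjusted p = 5.86e-06) and activity-regulated genes in 25 of 30 (median -0.36, 0 called on either adjustment, adjusted p = 2.46e-04). Commonly cited FMRP target mRNAs were positive in 59 of 77 (median 0.11, 4 higher and 1 lower over all genes, 7 and 1 adjusted over the list alone, adjusted p = 9.70e-05). Chromatin regulators were positive in 34 of 42 (median 0.12, 1 higher over all genes, 8 adjusted over the list alone, adjusted p = 7.61e-04). Vesicle release genes were positive in 35 of 54 (median 0.07, 1 higher over all genes, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0441). Oligodendrocyte markers were negative in 14 of 17 (median -0.17, 1 lower on either adjustment, adjusted p = 0.0387). The vesicle release call ended with a glial score (adjusted p = 0.0997) and without C3, C18 and C19 (adjusted p = 0.105). The oligodendrocyte call ended likewise (median -0.09, adjusted p = 0.1155, and median -0.13, adjusted p = 0.152), although the fit with a glial score is no independent test of a glial list. None of these 8 calls held with an estimated correlation, each at adjusted p = 0.968 with an estimated correlation. On scores per animal the smallest exact permutation p was 0.0227, for cholesterol synthesis (difference -0.19, adjusted p = 0.341, lower in 6 of 6 KO animals). The next exact permutation p was 0.0262, for ribosomal proteins (difference -0.17, adjusted p = 0.341, 6 of 6).

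**Figure D2:**
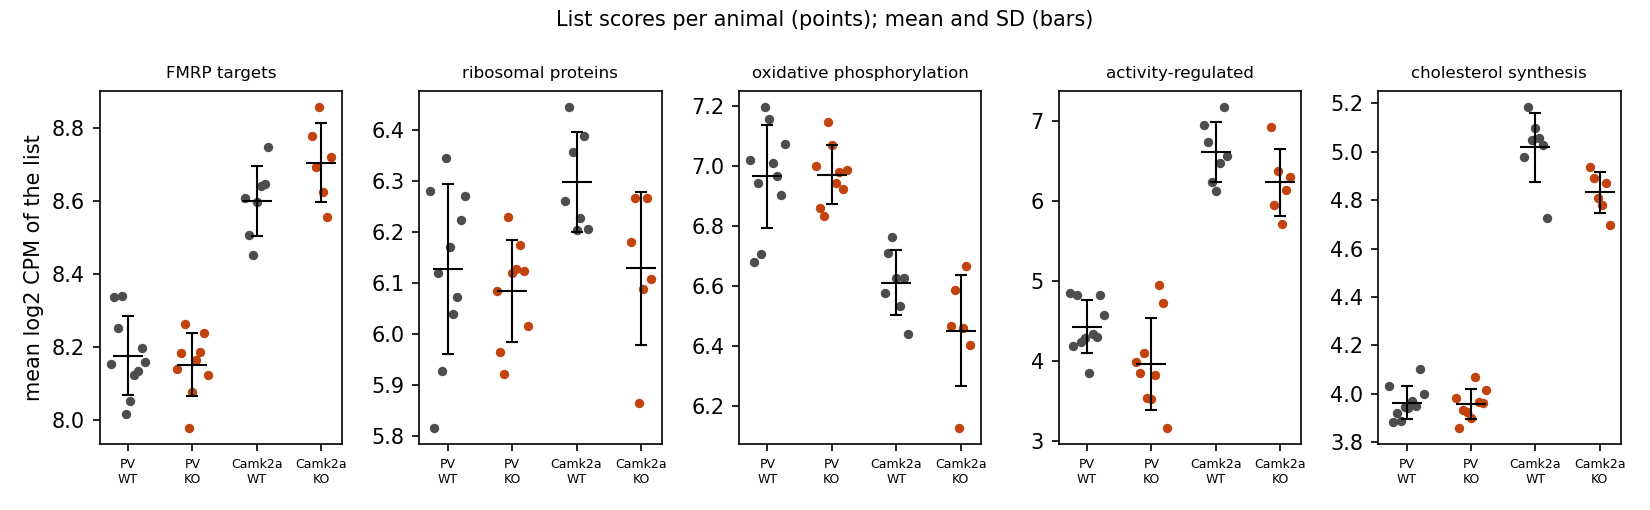
Mean log2 CPM per animal (y axis) of 5 gene lists in WT and KO animals of both cell classes (x axis), with points for animals and bars for the mean and SD. KO Camk2a animals differ on average by -0.17 from WT animals for ribosomal proteins and -0.19 for cholesterol synthesis.

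PV markers were negative in 16 of 17 in Camk2a KO animals with a median of -1.08, but the list did not pass (adjusted p = 0.122). Their level was set by 3 animals, the WT animals C18 and C19 and the KO animal C3, in which Pvalb reached 19.14 to 113.16 CPM. Lists that also did not pass were glutamate receptors (median 0.07, adjusted p = 0.0772), translation and mTOR (0.04, 0.484), mitochondrially encoded genes (0.09, 0.469), sodium, calcium and HCN channels (0.06, 0.342). The same holds for proteasome genes (0.02, 0.676), perineuronal nets (-0.12, 0.943), excitatory markers (-0.01, 0.943), vascular markers (-0.05, 0.783), red blood cell markers (-0.49, 0.430), oligodendrocyte precursors (-0.08, 0.943), potassium channels (-0.01, 0.923) and heat shock genes (-0.05, 0.283). Astrocyte (median 0.04, mean -0.00, 0.943) and microglia markers (0.05, mean -0.01, 0.943) had a negative mean and test with a positive median. Other interneuron markers (-0.08, mean 0.20, 0.943) and cAMP signalling genes (-0.00, mean 0.03, 0.756) had a positive mean and test with a negative median, and GABA synapse genes (-0.01, mean -0.13, 0.756) a positive test alone.

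**Figure D3:**
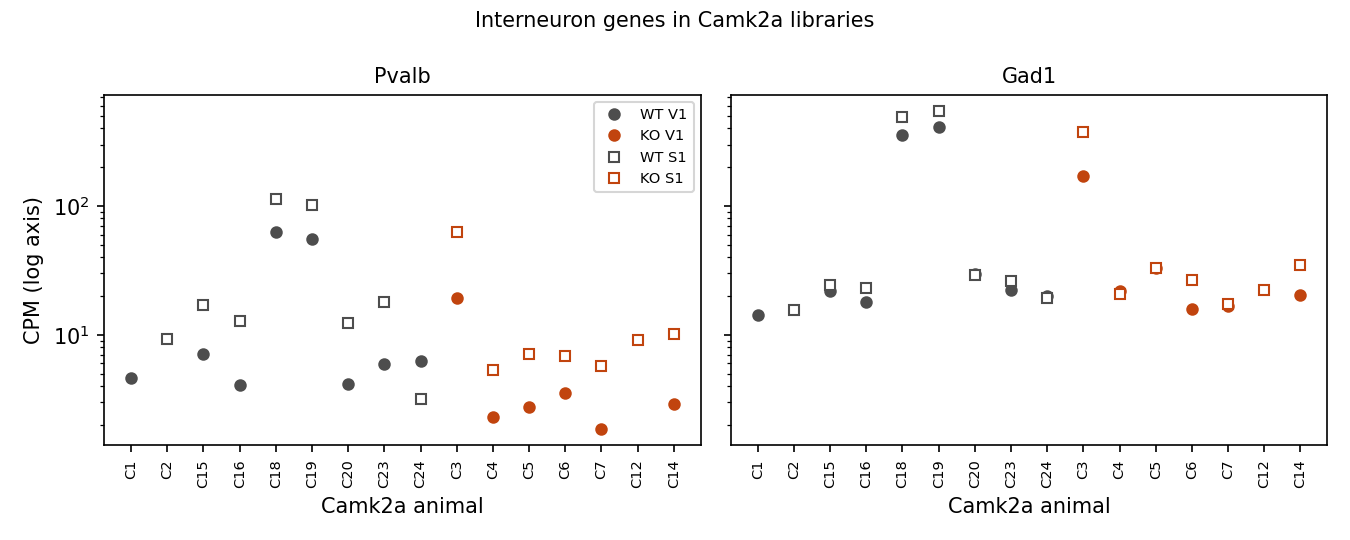
Pvalb and Gad1 in CPM (y axes, log scale) in the V1 (filled) and S1 (open) libraries of each Camk2a animal (x axes), WT in dark grey and KO in orange-red. C18, C19 and C3 reach 19.14 to 113.16 CPM of Pvalb and stand above the others in Gad1 in both areas.

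Within areas, Camk2a neurons gave 222 of 15816 genes in V1 (98 higher, 124 lower) and 641 of 15691 in S1 (313 higher, 328 lower), with 119 genes other than Fmr1 called in both areas and all 119 of the same sign (at most 1 in 100 draws with genotypes permuted over animals). In V1, Cdkn1c (1.12, adjusted p = 0.0495), Fam160a1 (1.11, adjusted p = 0.0052) and Sphkap (0.80, adjusted p = 0.0347) rose. In the same area Tcap (-1.73, adjusted p = 0.0310), the matricellular gene Ccn4 (-1.43, adjusted p = 0.0191) and the complexin gene Cplx1 (-0.52, adjusted p = 0.0414) fell, as did the respiratory subunit Ndufa1 (-0.36, adjusted p = 0.0480). In S1, the scaffold Akap6 (0.34, adjusted p = 0.0187) and the adenylyl cyclase Adcy9 (0.41, adjusted p = 0.0440) of the cAMP list rose. So did Slitrk3 (0.25, adjusted p = 0.0479), Cacnb4 (0.30, adjusted p = 0.0216) and Setd5 (0.24, adjusted p = 0.0383). The early response genes Egr2 (-1.52, adjusted p = 0.0313) and Jun (-0.64, adjusted p = 0.0091), the ubiquitin hydrolase Uchl1 (-0.35, adjusted p = 0.0187) and the isoprenoid enzyme Fdps (-0.42, adjusted p = 0.0245) fell.

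In V1 and S1, ribosomal proteins (71 of 78 and 75 of 78 negative, adjusted p = 2.30e-08 and 1.04e-08), oxidative phosphorylation (67 and 68 of 77 negative, 2.50e-06 and 4.98e-06) passed toward lower values. Passing likewise were cholesterol synthesis (22 of 25 negative in each, 1.17e-05 and 4.98e-06) and activity-regulated genes (25 and 26 of 30 negative, 3.14e-04 and 9.42e-05). FMRP targets (53 and 61 of 77 positive, 0.0140 and 4.98e-06) and chromatin regulators (33 and 34 of 42 positive, 0.0092 and 1.01e-04) passed toward higher values. In S1 alone, oligodendrocyte markers (lower, 0.0196), vesicle release genes (higher, 0.0270) and sodium, calcium and HCN channels (higher, 0.0385) passed as well. The difference between areas is tested separately. Of the FMRP list in S1, 4 genes rose over all genes and 18 adjusted over the list alone. Of the cholesterol list 4 fell over all genes and 12 adjusted over the list alone, and of the activity list 3 and 8. No list held with an estimated correlation, at adjusted p = 0.949 in V1 and 0.759 to 0.856 in S1 with an estimated correlation.

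Of the Camk2a genes named by area, Fam160a1 and Tcap in V1 and Egr2, Jun and Cacnb4 in S1 passed without C3, C18 and C19, and the others did not. The others kept their sign, in V1 at 1.30 (Cdkn1c), 0.76 (Sphkap), -1.44 (Ccn4), -0.43 (Cplx1) and -0.35 (Ndufa1). In S1 they stood at 0.33 (Akap6), 0.38 (Adcy9), 0.27 (Slitrk3), 0.23 (Setd5), -0.36 (Uchl1) and -0.44 (Fdps). With a glial score the calls of Egr2 (-1.44, adjusted p = 0.0555) and Adcy9 (0.41, adjusted p = 0.0583) in S1 and Cdkn1c in V1 (1.13, adjusted p = 0.0508) ended. Cdkn1c in V1 also lost its call without a filter on low counts (adjusted p = 0.0565), as did Ndufa1 (-0.36), and with sex by Y-linked genes (adjusted p = 0.0510), as did Setd5 in S1 (0.23). Slitrk3 in S1 lost its call with RLE size factors (adjusted p = 0.0509). In V1 the count was 876 with DESeq2, 15 without C3, C18 and C19, and 351 without C24. Leaving out other single libraries gave 474 (C14), 405 (C6), 125 (C20), 88 (C18), 75 (C3), 74 (C23), 66 (C15), 64 (C19), 45 (C5), 33 (C4), 30 (C7) and 28 (C16). In S1 it was 1454 with DESeq2, 990 without the sex term, 1634 without C24 and 299 without C3, C18 and C19. Without other libraries it was 387 (C23), 335 (C6), 305 (C5), 300 (C15), 277 (C7) and 253 (C16).

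The series title raises the question of opposite changes in inhibitory and excitatory neurons. Genes called in both classes moved the same way. Apart from Fmr1, all 41 such genes had 1 sign, 11 higher where independent lists would share 1.11 and 30 lower where they would share 3.52, and none was called in opposite directions where independent lists would share 1.07 and 3.66. They included Cd99l2, Gng4 and Cdkn1c, which rose, and Plch1, Hrh2, Ccnd2, Tcap, the lipoxygenase Alox8 and the calcium sensor Hpca, which fell. Cdkn1c lay near the floor in PV libraries, with WT and KO means of 0.57 and 0.98 CPM in V1 and 0.34 and 0.66 CPM in S1. In WT V1, Slc17a7 stood at 222.1 CPM in PV and 2546 CPM in Camk2a libraries. Whether RNA carried over from other cells adds to the shared calls was not tested. Without C3, C18 and C19 the genes called in both classes were 19, all 19 of 1 sign, and Gng4, Plch1, Hrh2 and Hpca were not among them. Without the sex term Tcap did not pass in PV (-0.51, adjusted p = 0.0723). Of 862 genes called in either class, Fmr1 left out, 727 (84.3%) had the same sign in the other. Across 16447 genes, which are not independent replicates, the genotype effects correlated at r = 0.226 (Spearman 0.269, covariance 0.00945), and with permuted genotypes the correlation had a median of 0.004 (-0.266 to 0.275), with 1 of 100 draws as high. Among genes of at least 5 CPM r was 0.299 (permuted median 0.009, -0.446 to 0.553, 7 of 100 draws as high). The classes share no animals.

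**Figure D4:**
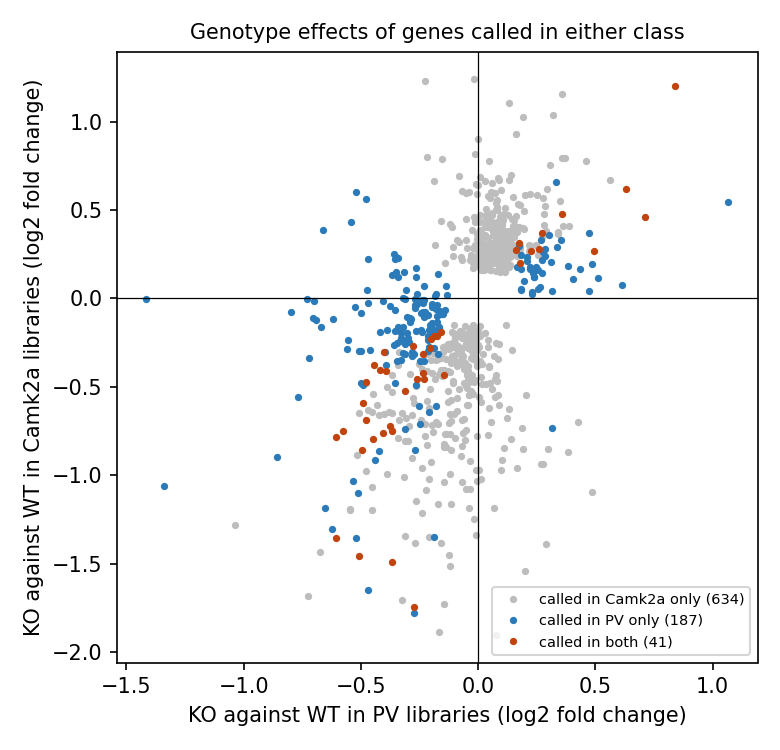
Log2 fold change of KO against WT in PV animals (x axis) and Camk2a animals (y axis) for the genes called in either class, with Fmr1 left out and each point a gene. The 41 genes called in both classes all lie in the quadrants of equal sign.

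A direct test of the difference found 146 of 17547 genes whose genotype effect differed between classes, 89 more positive in PV and 57 more positive in Camk2a. Sphkap had a log2 fold change of -0.22 in PV and 0.80 in Camk2a (difference -1.02, adjusted p = 0.0014) and Htr1a -0.19 and 0.67 (difference -0.85, adjusted p = 0.0105). Plau, a plasminogen activator, fell in PV (-0.36, adjusted p = 0.0049) and stood at 0.25 in Camk2a (adjusted p = 0.183; difference -0.59, adjusted p = 0.0134). Alox8 (-0.27 and -1.74, difference 1.47, adjusted p = 5.00e-04) and Aldoc (-0.14 and -0.84, difference 0.71, adjusted p = 0.0014) were lower mainly in Camk2a. Of the 146, 143 were in the tests of both classes, 85 had opposite signs, and 53 of these were called in 1 class. None, 0 of the 146, was called in both with opposite signs. That last count rests on edgeR, with 2043 and 3843 genes at unadjusted p under 0.05 in PV and Camk2a. Fmr1 itself differed (1.15, adjusted p = 6.85e-08). Its KO means were close in the classes, 10.4 and 9.795 CPM in PV and 8.479 and 8.65 CPM in Camk2a (V1 and S1). Its WT means were higher in Camk2a (84.42 and 77.75 CPM) than in PV (43.46 and 44.94 CPM). Rapgef4 did not differ (-0.02, adjusted p = 0.890, and 0.01, adjusted p = 0.9855, without C3, C18 and C19).

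The genotype effect on several gene lists differed between the classes in size or direction. Ribosomal protein genes had negative medians in both (-0.06 in PV and -0.15 in Camk2a), as did cholesterol genes (-0.02 and -0.21). For these 2 lists the difference is one of size and not of direction. The PV minus Camk2a difference was negative, so lower in PV, for 66 of 77 FMRP targets (median -0.14, adjusted p = 3.71e-07), 38 of 42 chromatin regulators (-0.14, 5.24e-07), and 41 of 53 glutamate receptor genes (-0.10, 6.82e-05). So it was for 13 of 13 mitochondrially encoded genes (-0.43, 0.0096) and 38 of 54 vesicle release genes (-0.06, 0.0328). It was positive for 69 of 77 oxidative phosphorylation genes (0.15, 5.19e-07), 23 of 25 cholesterol genes (0.18, 5.24e-07, 0 called over all genes and 7 adjusted over the list alone), 68 of 78 ribosomal protein genes (0.12, 1.92e-05) and 17 of 17 PV markers (0.95, 0.0363). Apart from 1 glutamate receptor gene, no member of these lists was called over all genes, and each list stood at adjusted p = 0.785 with an estimated correlation. Without C3, C18 and C19 the PV markers no longer passed (11 of 17 positive, median 0.09, adjusted p = 0.138). Vesicle release genes passed neither then (median -0.05, adjusted p = 0.138) nor with a glial score (median -0.04, adjusted p = 0.287). The median of the mitochondrially encoded genes was -0.75 with that score (adjusted p = 1.67e-05). Counts of differing genes were 268 with DESeq2, 228 with a glial score, 346 with limma-voom on libraries kept apart and the animal as a block, 268 without C24 and 92 without C3, C18 and C19, with 72 of the 92 among the 146.

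Whether the genotype effect differed between V1 and S1 was tested in each class, and no gene passed. In simulations of this test, 64% of genes changed 1.5 fold were recovered in PV and 56% in Camk2a. At 1.25 fold these shares were 38% and 12%, so differences of that size could be missed. With edgeR, 0 of 16733 genes passed in PV (312 at unadjusted p under 0.05, 0 with DESeq2 and limma-voom) and 0 of 16360 in Camk2a (608 at unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). The smallest p in PV were those of Fgfr1op (0.28, adjusted p = 0.9998) among higher and Zkscan17 (-0.21, adjusted p = 0.9998) among lower values, and in Camk2a those of the matrix gene Smoc2 (0.90, adjusted p = 0.870) and Proser2 (-0.81, adjusted p = 0.9998). By list, V1 minus S1 effects in PV were negative for 18 of 20 excitatory markers (adjusted p = 9.89e-05), mitochondrially encoded genes (0.0019) and ribosomal proteins (0.0068). The same direction passed for activity-regulated genes (0.0172), chromatin regulators (0.0172), glutamate receptors (0.0239) and FMRP targets (0.0388), at adjusted p = 0.952 with an estimated correlation. The lists were not tested again without the animals on the other area's side. In PV these were P9 and P24 (KO) and P22 (WT). Excitatory markers and the mitochondrially encoded, activity-regulated, chromatin, glutamate receptor and FMRP lists also passed toward higher values in V1 in WT PV libraries. An uneven mix of areas or carried-over RNA therefore cannot be told apart from a genotype effect that differs by area. In Camk2a the V1 minus S1 effects were positive for ribosomal proteins (5.55e-04) and proteasome genes (0.0069) and negative for sodium, calcium and HCN channels (9.03e-04), potassium channels (0.01) and FMRP targets (0.01), at adjusted p = 0.861 to 0.877 with an estimated correlation. Across genes, which are not independent replicates, V1 and S1 effects correlated at r = 0.351 in PV (permuted median 0.189, -0.126 to 0.588, 6 of 100 draws as high). Among genes of at least 5 CPM r was 0.60, with its own permuted median of 0.395 (-0.277 to 0.806, 9 of 100 draws as high). In Camk2a r was 0.599 (permuted median 0.359, 0.056 to 0.704, 3 of 100 as high).

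WT libraries separated the classes by their known markers. Pvalb was higher in PV libraries by a log2 fold change of 4.65 in V1 (SE 0.739, adjusted p = 2.67e-05, 10 of 10) and 4.15 in S1 (SE 0.697, adjusted p = 5.07e-05, 10 of 10). The GABA enzyme Gad1 was higher by 5.24 and 5.09 (adjusted p = 4.27e-05 and 1.16e-04). Both folds are lowered by C18 and C19 in the Camk2a WT group, which hold far more of these mRNAs than its other libraries. Without C3, C18 and C19 they were 6.26 (adjusted p = 1.59e-11) and 5.51 (adjusted p = 5.26e-09) for Pvalb and 7.26 (adjusted p = 7.07e-17) and 7.32 (adjusted p = 1.39e-19) for Gad1. The glutamate transporter Slc17a7 was lower by -3.46 and -4.07 (adjusted p = 1.00e-13 and 1.34e-19) and Camk2a by -2.59 and -3.04 (adjusted p = 1.24e-13 and 3.33e-20). In total 12618 of 16330 genes differed in V1 (6501 higher in PV, 6117 lower) and 12448 of 16131 in S1 (6303 higher, 6145 lower). All 17 PV markers were higher and all 20 excitatory markers lower in both areas. Of other interneuron markers, 7 of 14 were higher and 4 lower in PV libraries in V1, and 5 of 13 higher and 4 lower in S1, and the list did not pass (adjusted p = 0.689 and 0.815). Lamp5 (-4.06 and -3.97) and Id2 (-3.93 and -4.38) were among the lower ones.

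Markers of glia and vessels were higher in PV than in Camk2a WT libraries. In V1, 14 of 18 astrocyte markers were higher and 2 lower, with Mlc1 at 2.28 (adjusted p = 3.84e-11). Of oligodendrocyte markers, 16 of 17 were higher, with Mog at 2.21 (adjusted p = 6.47e-08), and 6 of 6 of their precursors', with Pdgfra at 2.30 (adjusted p = 9.10e-09). Higher were also 13 of 15 microglia markers, with C1qb at 2.65 (adjusted p = 2.21e-10), and 12 of 14 vascular markers, with Cdh5 at 3.20 (adjusted p = 2.74e-08). S1 gave 14 of 18, 16 of 17, 6 of 6, 13 of 15 and 12 of 15, while the astrocyte gene Aldh1l1 was lower there (-2.25, adjusted p = 6.33e-17). All 13 mitochondrially encoded genes were higher in both areas (median 2.85 and 2.01), and 22 and 28 of 30 activity-regulated genes were lower (median -2.01 and -2.51). Of the 17 and 15 lists that passed in V1 and S1, excitatory markers in S1 alone held with an estimated correlation (adjusted p = 0.0444), with adjusted p = 0.339 for them in V1.

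Between areas, WT PV libraries of V1 held more activity-regulated mRNA than those of S1. The excitatory marker Slc17a7 was also higher there, with means of 222.1 CPM in V1 and 144.7 CPM in S1. Whether RNA carried over from excitatory neurons adds to the activity-regulated difference was not tested. Fosb (2.32, SE 0.462, adjusted p = 0.0064), Nr4a3 (2.20, adjusted p = 0.0067), Fos (2.12, adjusted p = 0.0072) and Npas4 (1.91, adjusted p = 0.0070), all early response genes, were higher in V1 in 9 of 10 libraries. Btg2 (1.68, adjusted p = 0.0397) was higher in 8 of 10 and did not pass with limma-voom (1.35, adjusted p = 0.0895). Spp1 (-1.80, adjusted p = 0.0089), Kcng4 (-1.11, adjusted p = 0.0096) and the sodium channel subunit Scn4b (-0.98, adjusted p = 0.0117) were lower in V1 in 9 of 10. So were the vesicle protein Sv2c (-1.05, adjusted p = 0.0466) and Trarg1 (-1.17, adjusted p = 0.0060), with Sv2c at adjusted p = 0.0508 without a filter on low counts and 0.0546 without the sex term. Of perineuronal net genes, the pentraxin receptor Nptxr was higher (0.58, adjusted p = 0.0058), and Acan (-0.64, adjusted p = 0.0113) and Hapln4 (-0.31, adjusted p = 0.0126) were lower in V1, again in 9 of 10. In all, 3291 of 15964 genes differed, 1702 higher and 1589 lower in V1.

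Among the lists, 27 of 30 activity-regulated genes were higher in V1 PV libraries (29 higher and 1 lower adjusted over the list alone, adjusted p = 2.51e-12). At the same time, 46 of 77 oxidative phosphorylation genes were lower (74 adjusted over the list alone, adjusted p = 6.57e-18) and 17 of 38 proteasome genes were lower (24 adjusted over the list alone, adjusted p = 2.48e-09). Each stood at adjusted p = 0.380 with an estimated correlation. Markers of other cells rose with them in V1, astrocyte in 11 of 18 (adjusted p = 3.34e-05), excitatory in 13 of 20 (4.39e-05), vascular in 8 of 15 with 1 lower (3.35e-04) and microglia in 6 of 15 (3.66e-04), at adjusted p = 0.380 with an estimated correlation. Oligodendrocyte markers (3 of 17 higher, 1 lower, 0.0491), those of their precursors (4 of 6 higher, 1 lower, 0.0434) and of other interneurons (6 of 14 higher, 2 lower, 0.0450) passed toward higher values too, at adjusted p = 0.645, 0.380 and 0.380 with an estimated correlation. The mitochondrially encoded genes were positive in 13 of 13 (median 0.84, 0 called over all genes, 13 higher adjusted over the list alone, adjusted p = 1.30e-04, adjusted p = 0.487 with an estimated correlation). Glutamate receptor genes (0.0023), chromatin regulators (2.57e-04) and FMRP targets (0.0160) also passed toward higher and translation and mTOR genes (0.0019) toward lower values, at adjusted p between 0.380 and 0.645 with an estimated correlation. With the block on the animal in edgeR, 4243 genes differed and 3088 of the 3291 were among them. Without the animals on the other area's side the count was 5060, a value that is circular because those animals were chosen by area genes.

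The main fit gave fewer genes between areas in WT Camk2a than in WT PV libraries. The Camk2a count was unstable, as given below, so it does not rank the classes. Egr4, an early response gene, was higher in V1 (1.25, SE 0.244, adjusted p = 0.0452, 8 of 8). So were the transcription factor Gtf3a (1.08, adjusted p = 0.0362, 8 of 8), the calcium-activated potassium channel Kcnn3 (0.92, adjusted p = 0.0385, 7 of 8) and the synapsin gene Syn2 (0.33, adjusted p = 0.0433, 8 of 8). Lrrc57 (-0.55, adjusted p = 0.0498, 7 of 8), the keratin gene Krt12 (-0.55, adjusted p = 0.0468, 8 of 8) and Gnpda2 (-0.37, adjusted p = 0.0362, 8 of 8) were lower. In total 56 of 15607 genes differed, 40 higher and 16 lower. Activity-regulated genes were positive in 30 of 30 (median 0.56, 1 called over all genes, 6 adjusted over the list alone, adjusted p = 4.43e-09) and glutamate receptor genes in 42 of 53 (median 0.13, 0 called over all genes, 9 higher and 1 lower adjusted over the list alone, adjusted p = 2.45e-05). FMRP targets (0.0230), chromatin regulators (0.0230) and, toward lower values, oxidative phosphorylation (0.0455) also passed. These 5 lists stood at adjusted p = 0.990 with an estimated correlation.

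This count moved with the tool, the covariate, the block and the libraries left out. It was 1345 with DESeq2, 405 with limma-voom, 385 without the sex term, 310 with sex by Y-linked genes, 7 with the animal as a block (each gene named here then at an adjusted p of at least 0.127). It was 2727 without the Batch 2 library of C24, 3405 without both libraries of C24 (circular, since C24 was chosen by area genes) and 0 without C3, C18 and C19 (edgeR). In PV, P9 and P22, and in Camk2a, C24, had their V1 and S1 libraries on each other's side of the area score, and the V1 library of P24 lay on the S1 side. Sex-linked genes differed from the label in both libraries of P11 (labelled female), C16 (labelled male) and C23 (labelled female).

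**Figure D5:**
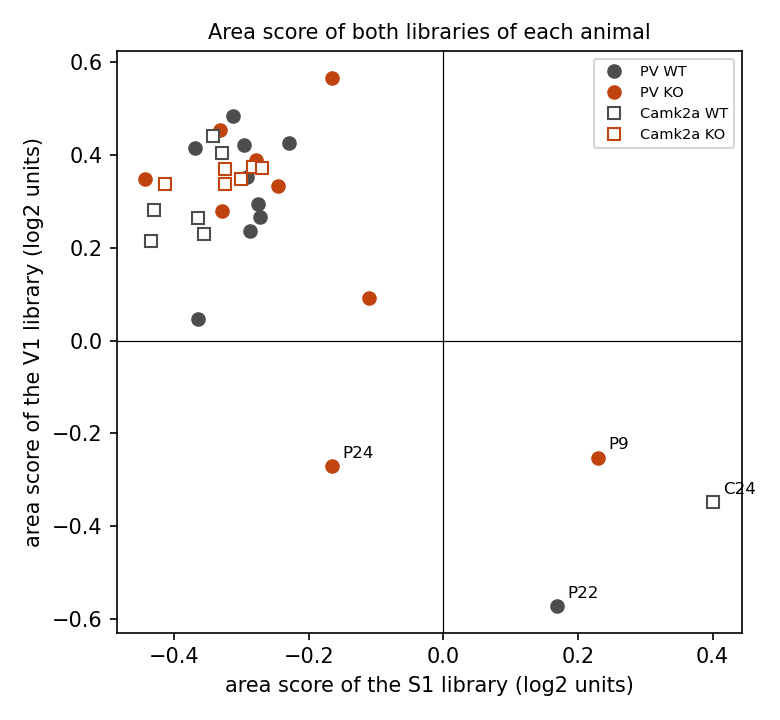
Area score of the S1 library (x axis) and the V1 library (y axis) of each animal with both, in log2 units, with PV animals as filled circles, Camk2a animals as open squares, WT in dark grey and KO in orange-red. P9, P22 and C24 fall in the lower right quadrant, where each library lies on the other area's side, and P24 in the lower left.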

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

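Of the tests below, those of RNA of other interneurons, of dissection across areas and of RNA of PV cells in C3, C18 and C19 were chosen after the results were seen. In 136 tests of single groups for a library far from the rest, 18 values stood apart, and chance gives about 1 in 20 groups.

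PV marker genes were high in both libraries of the Camk2a animals C3 (KO), C18 and C19 (WT). Pvalb in C3 reached 19.14 CPM in V1 and 62.29 CPM in S1 and Gad1 172.3 and 376.1 CPM, far from the other KO libraries. RNA of other interneurons carried along is excluded as the whole source, because their markers had a highest median log2 excess of 0.09 in these 6 libraries. A mixed-in PV library needs equal PV shares from both kinds of genes. The mean share was 9.8% from PV markers and -4.4% from glial, vascular and mitochondrially encoded genes, a gap of 14.2 percentage points. This gap argues against a mixture but does not exclude it, because the second share had an SD of 8.1 points over the 23 other Camk2a libraries. Recombination by Camk2a-Cre in PV cells of these animals may remain as an explanation and was not tested.

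The V1 and S1 libraries of P9, P22 and C24 lay on each other's side of the area score. A dissection that took tissue of both areas would bring V1 minus S1 toward 0 and is excluded for these 3, because the highest such difference among these animals was -0.482. Exchanged libraries are consistent with the data, since area genes taken from the other cell class also placed all 3 animals on the wrong side, at -0.318 or lower. P24, with its V1 library alone on the other side, had a V1 minus S1 of -0.105, nearer 0 than every other PV animal. Its scores were -0.271 for the V1 and -0.166 for the S1 library, so both lay on the S1 side. Such a dissection and a V1 library taken from S1 both give a small difference, so this value cannot decide between them. In P9, P22 and C24, single libraries stood apart from their group. P22 had 34.79 CPM of Nos1, 34.34 CPM of Ccnd2 and 11.99 CPM of Gng4 in S1 and 5.21 CPM of Gng4 and 5.996 CPM of Htr1a in V1, P9 had 20.57 CPM of Nos1 in S1, and C24 had 264.2 CPM of Rapgef4 and 17.9 CPM of Plch1 in V1.

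In Camk2a KO animals, FMRP target mRNAs lay toward higher and ribosomal protein and oxidative phosphorylation mRNAs toward lower levels. Exon length correlated with the log2 fold change over all genes (Spearman 0.208). Lists matched on length and expression had medians of 0.047, -0.074 and -0.081 where the 3 lists had 0.114, -0.151 and -0.144, in the same order. All 3 list medians lay outside the central 95% of the matched lists, which argues against length as the whole cause. Matched genes were drawn singly, so that range is too narrow where members of a list vary together. RNA of PV cells in C3, C18 and C19 is excluded as the whole cause, since without these animals the list medians were at least 0.87 of those with them. Variation between animals is consistent with the pattern and stays open, as the lowest adjusted exact permutation p of the 3 list scores was 0.341. Loss of FMRP, the biological difference in the design, stays open as well.

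Other single values far from their group were 184.2 CPM of Pvalb in P3 S1, 8365 CPM of Camk2a in C4 S1, 19.89 CPM of Nos1 in C7 S1, 6.587 CPM of Klhl14 in P11 V1, 125.4 CPM of Cd99l2 in P23 V1 and 237.9 CPM of Aldoc in P25 S1.

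The genotype effect differed between PV and Camk2a, by a direct test, in 146 genes. PV minus Camk2a log2 differences were 1.15 for Fmr1, 1.2 for Ccn4, 1.47 for Alox8, 0.64 for Rcn1, 0.34 for Galnt11, 0.71 for Aldoc, 0.42 for Pkp4, 0.63 for Dusp16, 0.53 for Fam196a and 0.56 for Tgfb3. They were -1.02 for Sphkap, -0.48 for Wls, -0.50 for Klf5, -0.36 for Gaa, -0.85 for Htr1a, -0.59 for Plau, -0.53 for Pgm1, -0.34 for Cdh2, -0.32 for Ptcd1 and -0.31 for Sphk2. With limma-voom on libraries kept apart and the animal as a block, Dusp16 (0.49), Klf5 (-0.50) and Gaa (-0.28) no longer passed, and without C3, C18 and C19 Sphk2 (-0.28, adjusted p = 0.0594) did not.

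Other splits of the same samples, 100 per comparison with the real split included, were refitted. No other split gave as many genes as the real one for PV S1 (122, highest other split 1), Camk2a V1 (222, highest other 21) and Camk2a S1 (641, highest other 6). The same held for PV over both areas (234, highest other 1) and the areas in PV WT (3291, highest other 0). It also held for the class comparison in V1 (12618, highest other 5460) and S1 (12448, highest other 7217). In these comparisons chance was an unlikely source of the count. As many genes came from 2 of 100 splits, the real one included, for PV V1 (31, highest other split 1065) and Camk2a over both areas (688, highest other 1270). The same held for the difference between classes (146, highest other 164) and the areas in Camk2a WT (56, highest other 1047). In each of these another split passed the real count, so chance is unlikely but not excluded. With the animal as a block, the areas in Camk2a WT gave 7 genes, 4 of them among the 56. The composition of the other splits with high counts was not examined. For those above the real count, a structure of the samples other than genotype or area stays open. Among splits that part every V1 and S1 pair, 3 of 100 gave as many genes as the areas in PV WT (highest other 5259) and 4 of 100 as the areas in Camk2a WT (highest other 3515). In both area comparisons another of these splits passed the real count, so chance is unlikely but not excluded, in PV WT as well. For the difference between areas of the genotype effect, the real split gave 0 genes (highest other 2 in PV and 60 in Camk2a), so all 100 splits necessarily gave as many or more, and the count decides nothing about chance.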

How the results depend on the processing

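Sex by Y-linked genes, leaving out C3, C18 and C19, and leaving out the animals on the other area's side were chosen after seeing the data. Fmr1 was called under every alternative. Over 341 values of named genes other than Fmr1 and Rapgef4, recomputing under other settings kept the side of the threshold 2866 times and lost it 171 times, and leaving out single libraries or animals kept it 2028 times and lost it 622 times, with no sign reversed among these 341. Rapgef4 did change sign in 1 comparison, given below. Where a count moved, the cause was not tested, except that settings with fewer samples have less power. With limma-voom on libraries kept apart and the animal as a block, 12 calls of named genes made on the summed animals were lost, and 12 between areas with the block in edgeR. Library totals ran from 27.64 to 49.11 M estimated counts, with the Batch 2 library (C24 S1) the lowest. Batch 2 holds 1 library, so it allows no value within the batch.

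With DESeq2 the counts were 113 (PV V1), 308 (PV S1), 876 (Camk2a V1), 1454 (Camk2a S1), 476 (PV both areas), 1743 (Camk2a both areas), 268 (difference between classes), 1 (difference between areas in Camk2a) and 1345 (areas in Camk2a WT). With a glial score they were 137 (PV V1), 384 (PV both areas) and 228 (difference between classes). With limma-voom the areas in Camk2a WT gave 405 genes, without the sex term 385 (and 990 in Camk2a S1), and with sex by Y-linked genes 310 (and 48 in PV V1). With limma-voom on libraries kept apart and the replicate block, where the tool, the unit and the block change together, they were 411 (PV both areas), 1949 (Camk2a both areas) and 346 (difference between classes). With the replicate block in edgeR the areas in Camk2a WT gave 7.

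Without the Batch 2 library the counts were 1634 (Camk2a S1), 1347 (Camk2a both areas), 268 (difference between classes) and 2727 (areas in Camk2a WT). Without C3, C18 and C19 they were 15 (Camk2a V1), 299 (Camk2a S1), 131 (Camk2a both areas), 92 (difference between classes) and 0 (areas in Camk2a WT, edgeR). Without animals on the other area's side they were 81 (PV S1), 351 (Camk2a V1), 1634 (Camk2a S1), 5060 (areas in PV WT) and 3405 (areas in Camk2a WT), the last 2 circular. Leaving out single libraries or animals gave 20 to 56 (PV V1), 80 to 177 (PV S1), 28 to 474 (Camk2a V1), 253 to 1634 (Camk2a S1), 144 to 255 (PV both areas) and 235 to 1347 (Camk2a both areas).

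Rapgef4 passed in Camk2a S1 with DESeq2 (0.20), without the sex term (0.21) and without the Batch 2 library or the animals on the other area's side (0.19), in PV over both areas with DESeq2 (0.12), a glial score (0.12) and limma-voom with the replicate block (0.11), and in Camk2a over both areas with that limma-voom fit (0.18). Its difference between classes turned to 0.01 without C3, C18 and C19. With single libraries or animals left out its log2 fold change was 0.11 to 0.15 (PV V1), 0.09 to 0.11 (PV S1), 0.12 to 0.19 (Camk2a V1), 0.18 to 0.23 (Camk2a S1), 0.11 to 0.13 (PV both areas) and 0.11 to 0.18 (Camk2a both areas). Fmr1 lay between -2.13 and -2.01, -2.21 and -2.13, -3.37 and -3.26, -3.18 and -3.12, -2.13 and -2.05, and -3.28 and -3.19 in the same order. With an estimated correlation, 0 lists passed in every comparison except 1 in the class comparison in S1. The correlation of V1 and S1 effects in PV was 0.60 among genes of at least 5 CPM, where permuted genotypes gave a median of 0.395 and 9 of 100 draws as high.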
